A study of Arabidopsis thaliana with 12 samples.

How the data were processed

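RNA of Arabidopsis T87 suspension cells was measured on 12 single-colour Affymetrix arrays, 3 in each of 4 treatment groups. The groups and replicate numbers came from the sample labels. Biotin-labelled material was made from total RNA with a 3' labelling kit, per the labels' protocols. The values used were the authors' deposited log2 probe set values. RMA and limma are named, without a role or a version, per the submitters' processing notes. RMA corrects background, equalises the distributions of arrays normalized together and summarises the probes of a probe set. Whether all 12 arrays were normalized together was not given in the sources used here. The medians of the 12 arrays lay between 5.78 and 6.05 on the log2 scale, and no further normalization was applied. The number of arrays limits the precision.

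The table held 22810 probe sets. The 64 control probe sets were left out of the tests, which left 22746. Gene names came from the annotation table supplied with the platform, updated through a table of Arabidopsis genes. It named 1 gene for 13513 probe sets and several genes for 503, and 8730 probe sets are unnamed here. Of the probe sets with 1 gene, 13436 were matched to the gene table. Only 1581 had a symbol other than the locus identifier, and no gene was named from a probe set with several genes. Coverage favoured poorly known genes: 14.6% of protein-coding genes with a symbol had a named probe set, against 63.1% of those without one. Well-studied genes missing from the text are therefore mostly unnamed here, not unchanged. No genome build was named, so no coordinates are given.

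Each probe set was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 12 arrays and 8 residual degrees of freedom. Contrasts were ABA against control, ABA+DMTU against DMTU, ABA+DMTU against ABA, DMTU against control, and the interaction, which is the ABA effect with DMTU minus the ABA effect without it. Tests were two-sided moderated tests (eBayes). A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05, and the number that also changed at least 2-fold stands beside it. Errors given with a log2 change are standard errors from this fit, and errors given with a group level are standard deviations over 3 arrays. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels name no batch, and every array with DMTU could share one that the arrays without it did not. Spike-in controls, which do not come from the cells, were higher on average in the arrays with DMTU. The bioB level was 6.99 ± 0.29 in control, 7.3 ± 0.39 in ABA, 7.71 ± 0.13 in DMTU and 7.91 ± 0.38 in ABA+DMTU arrays. For cre these were 13.09 ± 0.09, 13.15 ± 0.14, 13.27 ± 0.11 and 13.38 ± 0.22. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

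The groups share replicate numbers and the pairing was checked. Deviations from the group mean correlated across probe sets between same-numbered control and ABA arrays, with r = 0.52, 0.42 and 0.39 for numbers 1, 2 and 3. Number 1 had -0.47 at most with another number, but numbers 2 and 3 reached 0.44 and 0.41 with another number, so the values set number 1 apart and do not tell 2 from 3. Deviations within a group cancel, so a number 1 that stands out in both groups tends by itself to make the values at 2 and 3 positive. By the rule fixed beforehand the numbers pair these groups, as a hint from the data, since no label says what a number marks. No other comparison had same-numbered correlations above 0.1 at every number. The replicate number as a block was run as an alternative.

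The designs, the alternatives, the rule for named genes and 26 gene lists of 444 genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among probe sets with 1 gene and a symbol that passed the test, changed at least 2-fold and did not overlap between the groups compared. Without an effect, 10% of probe sets in 3 against 3 arrays would not overlap. The interaction was ranked by size alone. The rule added up to 2 members of each fixed list with a call, and 14 ABA and oxidative stress genes whatever their result, of which COR15A was the one with a named probe set. The separation of genes with a symbol from those known by locus alone was made after the annotation was seen. The naming of 6 locus-only genes per direction, and the choice of list members as examples, came after values were seen. Of the 444 listed genes, 71 had a named probe set. Of the 26 fixed lists, 7 had none: ABA receptors, clade A PP2C phosphatases, ABA biosynthesis and breakdown, raffinose and proline synthesis, salicylic acid and immune response, xylem markers and embryo regulators. To describe groups despite this, 17 lists of gene families and of organelle-encoded genes were added after coverage was seen and before any test was run. The 2 lists used for hypotheses were written after the largest changes were seen.

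Lists with at least 3 members were tested against the other probe sets with camera at its preset correlation of 0.01, adjusted over all list tests. Camera was also run with the correlation estimated from the residuals, and fry tested each list by itself. All 26 list calls made at the preset correlation were lost with the estimated one, and 0 lists were called there. Estimated correlations reached 0.67 for cytosolic ribosomal proteins. The LEA and ABA marker list had -0.07, below the preset. Its call in ABA against control was lost too (camera adjusted p = 6.36e-06 and 0.106). A higher correlation therefore does not account for every loss. Fry, which asks whether the members move one way and compares them with no other gene, passed 20 of the 26.

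Alternatives were quantile normalization of the 12 columns, centring each array on its median, eBayes with a trend and robust spread, array quality weights, leaving out the 30% dimmest probe sets, probe sets of 1 gene only and without cross-hybridising types, the replicate block, fits of the 6 arrays compared, a stricter adjusted p of 0.01, the mean over all probe sets of a gene, and leaving out each array in turn. Leaving out replicate 1 of both the control and the ABA group, and a block in the 6-array fit of ABA against control, were added after the data were seen. The fit was tested on simulated data with 22746 probe sets, of which 50 were changed at each size. At a log2 change of 1 it recovered 74% in ABA against control and 52% for the interaction. At a log2 change of 2 these were 96% and 92%. It called 7 and 3 unchanged probe sets. The simulated noise was independent between probe sets and arrays, without arrays that deviate as a whole, and far fewer probe sets were changed than were called in the data. These shares may therefore not carry over to the data. The protein measurements named in the study's goals were not analysed here.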

Results

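T87 cells, an Arabidopsis suspension culture of the Columbia background, were sampled at 5 days of culture after 20 h of treatment. Control cells received ethanol, and the other groups received 50 µM abscisic acid (ABA), the hormone of drought and seed dormancy, 5 mM dimethylthiourea (DMTU), used by the study as a scavenger of hydrogen peroxide, or both. Each of the 4 groups had 3 arrays. The leading principal component held 69.2% of the variance and parted arrays with ABA from those without it, and the next held 12.9% and parted arrays with DMTU from those without it. Replicate 1 of the control group stood apart: its differences from replicates 2 and 3 had SDs of 0.565 and 0.550 on the log2 scale, against 0.167 between replicates 2 and 3. Replicate 1 of the ABA group did too, with 0.505 and 0.465 against 0.174. A sign of RNA quality from control probe sets, the 3' minus 5' log2 difference, moved with DMTU for ubiquitin and the other way with ABA. A GAPDH pair showed no such shift with DMTU, at 0.45 ± 0.1 in control, 0.59 ± 0.07 in ABA, 0.41 ± 0.19 in DMTU and 0.64 ± 0.45 in ABA+DMTU arrays. The others of the 6 pairs averaged higher with DMTU, without and with ABA. A second actin pair had 0.76 ± 0.14, 0.94 ± 0.08, 1.09 ± 0.05 and 1.29 ± 0.13 in the same order. A second ubiquitin pair had 0.33 ± 0.07, 0.3 ± 0.1, 0.47 ± 0.05 and 0.56 ± 0.15. For a second GAPDH pair the rise without ABA, from -0.07 ± 0.19 to 0.02 ± 0.05, lay within the spread. The 3' minus 5' log2 difference of ubiquitin was 0.92 ± 0.08 in control, 0.67 ± 0.04 in ABA, 1.36 ± 0.07 in DMTU and 1.1 ± 0.07 in ABA+DMTU arrays (SD, n = 3).

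**Figure D1:**
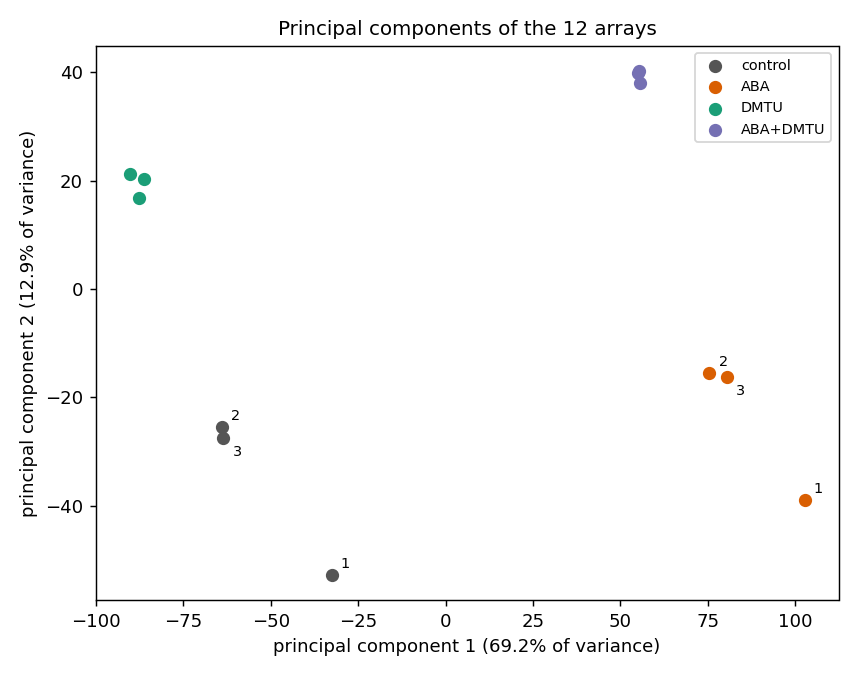
Scores of the 12 arrays on the leading principal components of the 22746 probe set log2 values, which hold 69.2% (horizontal axis) and 12.9% (vertical axis) of the variance, with 3 arrays per treatment group. Replicate 1 of the control group, at -32.59 and -52.74, lies apart from control replicates 2 and 3, at -63.93 and -25.47 and at -63.54 and -27.49.

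The comparison of ABA with control answered the study's opening question, which genes ABA regulates in these cells. Several transcripts of dehydration-protective proteins rose strongly, and cell cycle transcripts and 3 expansins fell. LEA4-5 (AT5G06760), a late embryogenesis abundant (LEA) protein, went from a log2 level of 4.41 ± 0.55 to 12.55 ± 0.09 (SD, n = 3), a change of 8.14 ± 0.25 (SE; adjusted p = 3e-09, limma). The dehydrins LTI30 (AT3G50970) and COR47 (AT1G20440) rose by 6.47 ± 0.50 and 4.56 ± 0.45, and the chloroplast-protective COR15A (AT2G42540) by 4.96 ± 0.27. The other large rises among genes with a symbol were the senescence-associated sugar transporter SAG29 (7.11 ± 0.19), the carboxylesterase CXE18 (5.88 ± 0.33), the purple acid phosphatase PAP20 (5.80 ± 0.37), ZW9 (5.48 ± 0.51), the beta-glucosidase BGLU45 (5.13 ± 0.31) and the sulfurtransferase STR18 (4.98 ± 0.38). GH3.5, which conjugates auxin to amino acids, rose by 4.01 ± 0.21. Among genes known by locus alone, AT3G22620 rose by 8.47 ± 0.46 and AT3G02480, of the LEA family, by 7.92 ± 0.67. Of the 6 measured LEA and ABA marker genes, 5 rose, and 5 rose adjusted over the list alone (camera adjusted p = 6.36e-06, and adjusted p = 0.106 with an estimated correlation). COR15B, the other member, had a change of 0.42 ± 0.21. Of the 37 measured members of the LEA family, which include these markers, 20 rose and AT2G46140 (-3.84 ± 0.36) and AT1G54410 (-3.40 ± 0.71) fell (camera adjusted p = 2.7e-07, and adjusted p = 0.124 with an estimated correlation).

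The wall-loosening expansins EXPA4, EXPA8 and EXPA15 fell with ABA, by changes of -4.40 ± 0.66, -4.15 ± 0.47 and -4.09 ± 0.33. The other large falls among genes with a symbol were the peroxidase Prx37 (-5.27 ± 0.63), the endoglucanase GH9C2 (-5.10 ± 0.30), the mitotic chromosome protein 3xHMG-box2 (-4.77 ± 0.32), TBL36 of a wall acetylation family (-4.57 ± 0.23) and the glycosyltransferase UGT73D1 (-3.93 ± 0.33). All 4 measured cell cycle genes fell, among them the replication factor PRL (-3.54 ± 0.18) and the mitotic kinase AUR1 (-3.33 ± 0.32), and 4 fell adjusted over the list alone (camera adjusted p = 0.000544, and adjusted p = 0.484 with an estimated correlation). Of 102 cytosolic ribosomal protein genes, 96 fell and 0 rose, with a median change of -0.91 (camera adjusted p = 2.36e-23, and adjusted p = 0.598 with an estimated correlation). Of 9 core histone genes, 6 fell, among them HTB2 (-3.87 ± 0.53). The histone list passed with camera (adjusted p = 0.0136, and adjusted p = 0.598 with an estimated correlation), and not once dim probe sets were left out (adjusted p = 0.0567). The expansin and xyloglucan endotransglucosylase list as a whole did not pass: 3 of 9 members fell, and its median of -0.11 became 0.04 with arrays centred on their medians.

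In ABA against control, limma called 8014 of 22746 probe sets, 3518 higher and 4496 lower, and 3764 of them changed at least 2-fold (1659 higher and 2105 lower). The split depended on scaling: with each array centred on its median, 5036 were higher and 3522 lower, since centring moved the median change of all probe sets by 0.15. With array quality weights the count was 12891. The 3' minus 5' difference of actin was 2.65 ± 0.09 in ABA and 3.2 ± 0.46 in control arrays (SD, n = 3). Another actin pair went the other way, with 0.94 ± 0.08 in ABA and 0.76 ± 0.14 in control arrays, as did a GAPDH pair, with 0.59 ± 0.07 and 0.45 ± 0.1.

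**Figure D2:**
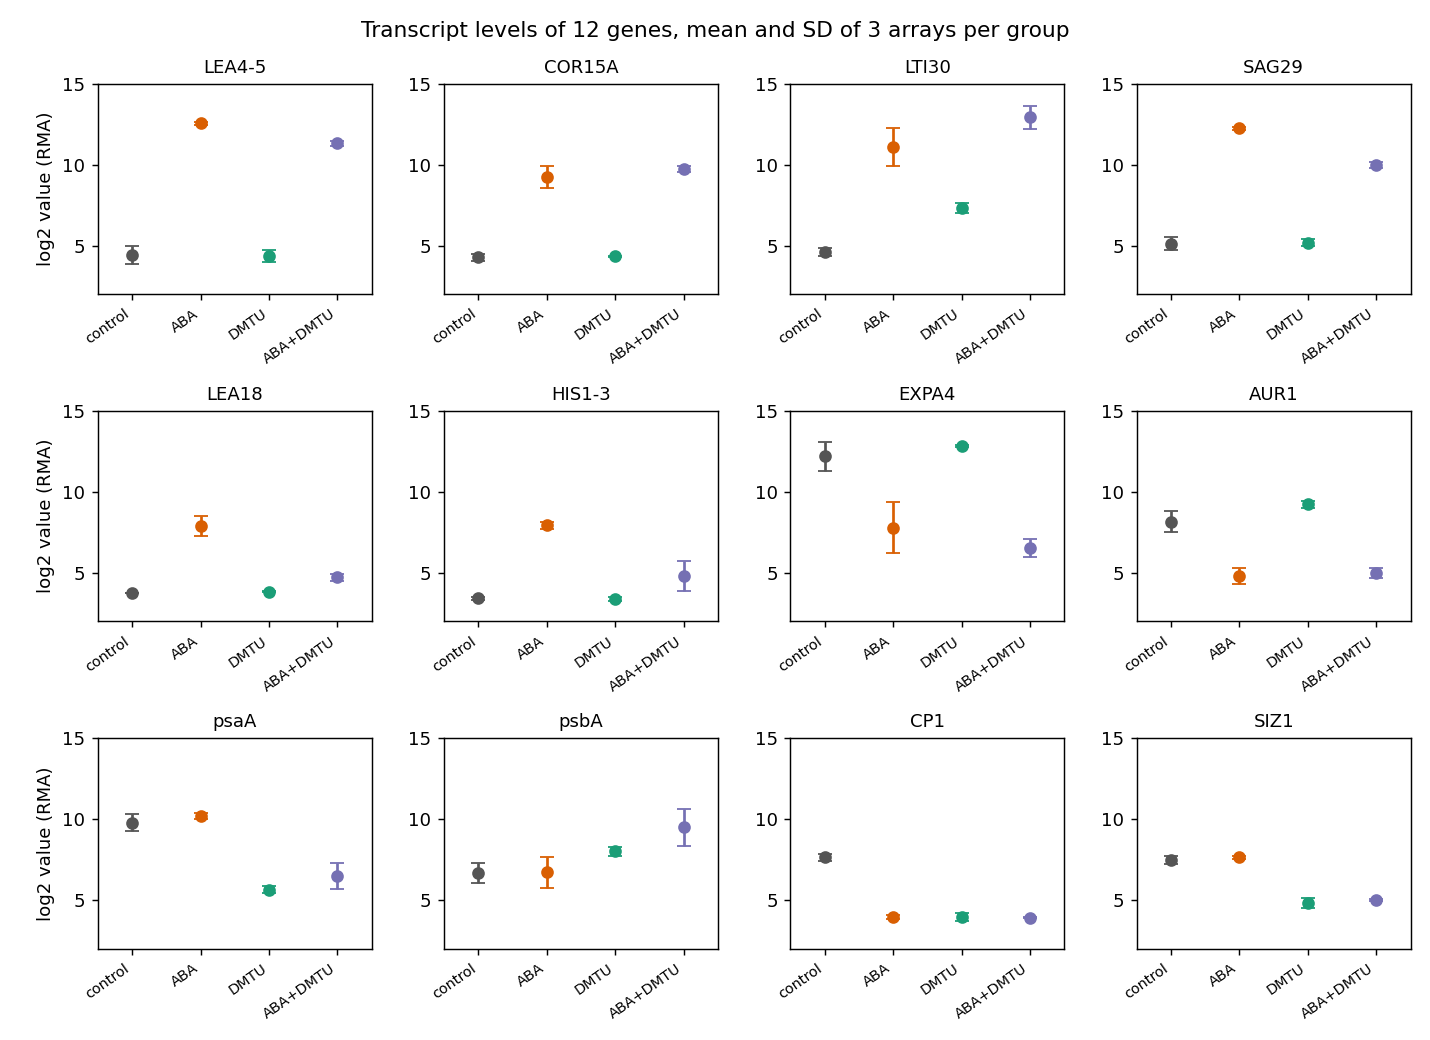
Log2 levels (vertical axes) of 12 named genes in the control, ABA, DMTU and ABA+DMTU arrays, with a point at the mean of each group and a bar for its SD (n = 3). LEA18 averages 7.89 with ABA and 4.73 with ABA and DMTU, while COR15A averages 9.23 and 9.75.

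The same ABA treatment was compared in cells that also received DMTU, with arrays that share none with the comparison above. The same kinds of transcript moved. LEA4-5 rose by 6.93 ± 0.25, COR47 by 6.17 ± 0.45, LTI30 by 5.60 ± 0.50 and COR15A by 5.43 ± 0.27. Formate dehydrogenase FDH (AT5G14780) rose by 5.71 ± 0.10, BGLU45 by 5.67 ± 0.31, GH3.5 by 4.86 ± 0.21 and the sugar transporter-like SFP1 by 4.85 ± 0.39, and these 8 rises had adjusted p of 6.01e-06 or less (limma). All 6 measured LEA and ABA marker genes rose, and 6 adjusted over the list alone (camera adjusted p = 0.000103, and adjusted p = 0.120 with an estimated correlation). Of the 37 LEA family members 15 rose and 1, AT2G46140, fell by -4.06 ± 0.36 (camera adjusted p = 0.000831, and adjusted p = 0.452 with an estimated correlation). The largest falls among genes with a symbol were EXPA4 (-6.29 ± 0.66), 3xHMG-box2 (-5.23 ± 0.32), Prx37 (-4.96 ± 0.63), GH9C2 (-4.96 ± 0.30), EXPA15 (-4.32 ± 0.33), TBL36 (-4.27 ± 0.23), AUR1 (-4.25 ± 0.32) and NDB4 (-4.08 ± 0.62). All 4 cell cycle genes fell, and 4 adjusted over the list alone (camera adjusted p = 0.000174, and adjusted p = 0.452 with an estimated correlation).

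With DMTU present, 99 of 102 cytosolic ribosomal protein genes fell with ABA, with a median of -1.21 (camera adjusted p = 6.41e-28, and adjusted p = 0.598 with an estimated correlation), and 8 of 9 core histone genes fell (camera adjusted p = 0.000106, and adjusted p = 0.452 with an estimated correlation). Of 69 plastid-encoded genes, 19 rose and 0 fell, with a median of 0.67 (camera adjusted p = 0.00059, and adjusted p = 0.751 with an estimated correlation). The plastid list did not pass without replicate 1 of ABA+DMTU (adjusted p = 0.052) or with fry (adjusted p = 0.127). Limma called 8956 probe sets, 4274 higher and 4682 lower, of which 4221 changed at least 2-fold (1833 higher and 2388 lower). Centring each array on its median gave 6753 higher and 3765 lower, with the median change of all probe sets moved by 0.17.

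The study's next question was how DMTU alters gene activation by ABA. Most ABA-induced probe sets were still induced with DMTU, while a minority rose much less. Of 1659 probe sets induced at least 2-fold by ABA alone, 1371 (82.6%) were also called higher with DMTU present. Of the 2105 lowered at least 2-fold, 1871 (88.9%) were also called lower. Across all probe sets the ABA changes without and with DMTU correlated (r = 0.86, rho = 0.80), and probe sets are not independent replicates. The calls shared 2646 rises and 3579 falls, where independent lists would share 661 and 925, and the opposite calls were 21 and 18.

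The interaction tested the difference itself. LEA18 (AT2G35300), an LEA protein, went from 3.75 ± 0.02 to 7.89 ± 0.61 with ABA alone, and from 3.84 ± 0.04 to 4.73 ± 0.22 with DMTU present (SD, n = 3), an interaction of -3.25 ± 0.34 (SE; adjusted p = 0.000673, limma). The ABA- and drought-induced linker histone HIS1-3 had -3.09 ± 0.49, SAG29 -2.31 ± 0.27, the starch synthesis subunit APL4 -2.18 ± 0.32, the carboxypeptidase-like scpl28 -2.07 ± 0.29, the outer envelope protein ATOEP16-2 -2.02 ± 0.25 and the ubiquitin ligase PUB19 -1.70 ± 0.26. Of the LEA family, 9 of 37 members had a negative interaction and 0 a positive one, and adjusted over the list alone 12 and 2, with AT3G15670 at -4.43 ± 0.25 (camera adjusted p = 0.000865, and adjusted p = 0.452 with an estimated correlation). AT3G15670 lay at 3.42 to 3.62 in all groups but ABA, and it and the LEA18 and HIS1-3 levels without ABA were at or below the lower quartiles of the arrays (3.84 to 3.98), so the sizes of these differences may be bounded by the low end of the scale, which was not measured. COR15A had 0.47 ± 0.39 (adjusted p = 0.651), so no difference in its response was detected. ABA induced these more with DMTU than without it: FDH (1.77 ± 0.15), the pectin methylesterase PMEPCRF (2.25 ± 0.25), the root bHLH regulator UPB1 (1.84 ± 0.33) and TBL25 (1.25 ± 0.20). For PMEPCRF the levels with ABA were alike, 10.61 ± 0.26 without and 10.62 ± 0.31 with DMTU, and the starting levels differed, 8.83 ± 0.03 in control and 6.59 ± 0.21 in DMTU arrays. FDH and TBL25 also started lower with DMTU, by changes of -1.39 and -0.92 in DMTU against control, and no such change was detected for UPB1 (-0.13, adjusted p = 0.749). The receptor kinase SD1-29 (1.48 ± 0.26) turned from -0.69 with ABA alone to 0.79 with DMTU present. The cysteine protease CP1 had 3.64 ± 0.20, with a level of 7.63 ± 0.21 in control arrays and 3.93 ± 0.13 in ABA, 3.97 ± 0.24 in DMTU and 3.91 ± 0.03 in ABA+DMTU arrays, the latter 3 near the same lower quartiles.

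Several lists had an interaction with camera. The histone list had a median of -0.68, with 1 member passing and 3 adjusted over the list alone (adjusted p = 0.000624, and adjusted p = 0.484 with an estimated correlation). The cell cycle list had -1.01, with 1 member passing and 2 adjusted over the list alone (adjusted p = 0.00886, and adjusted p = 0.598 with an estimated correlation). The photosynthesis list had 0.88, with 0 of 5 members passing and 3 adjusted over the list alone (adjusted p = 0.00213, and adjusted p = 0.484 with an estimated correlation). The ribosomal protein list had -0.26 with 0 members passing (adjusted p = 3.5e-06, and adjusted p = 0.739 with an estimated correlation), and was lost without control replicate 1 (adjusted p = 0.0666) and with fry (adjusted p = 0.376). The plastid-encoded list had 0.44 with 0 members passing (adjusted p = 9.61e-05, and adjusted p = 0.739 with an estimated correlation). It was lost without control replicate 1 (adjusted p = 0.0666), without ABA+DMTU replicate 1 (adjusted p = 0.0948) and with fry (adjusted p = 0.390). The trichome birefringence-like list had 0.26, with 2 of 22 members passing (adjusted p = 0.0448, and adjusted p = 0.598 with an estimated correlation). That call was lost with the replicate block (adjusted p = 0.0627), without both arrays numbered 1 (adjusted p = 0.118) and without any of control 1, control 3, ABA 1, DMTU 1, ABA+DMTU 1 and ABA+DMTU 2 (adjusted p from 0.0526 to 0.0973).

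Limma called 638 probe sets for the interaction, 263 positive and 375 negative, and 458 had an interaction of at least 2-fold. The count was 416 without control replicate 2, 385 without control 3, 343 without ABA 3, 395 without DMTU 1, 291 without DMTU 2, 370 without ABA+DMTU 2 and 411 without ABA+DMTU 3. It was 1243 without both arrays numbered 1 of the control and ABA groups. With array quality weights it was 3097, and the balance turned, with 1586 positive and 1511 negative. Among the 1659 probe sets induced by ABA alone, 203 (12.2%) had a smaller effect with DMTU and 46 a larger one, and the slope of the effect with DMTU on that without it was 0.762. Among the 2105 lowered, 61 had a smaller and 47 a larger effect, with a slope of 1.013. The choice of probe sets mattered. Among 1833 chosen instead as induced in ABA+DMTU against DMTU, 69 (3.76%) had a smaller effect with DMTU and 128 a larger one, with a slope of 0.911. Among 1740 chosen on the average of both effects, 164 had a smaller and 87 a larger one, with a slope of 0.802. For lowered probe sets these choices turned the balance: of 2388 chosen in ABA+DMTU against DMTU, 10 had a smaller and 120 a larger effect (slope 1.127), and of 2211 chosen on the average, 33 and 80 (slope 1.068).

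**Figure D3:**
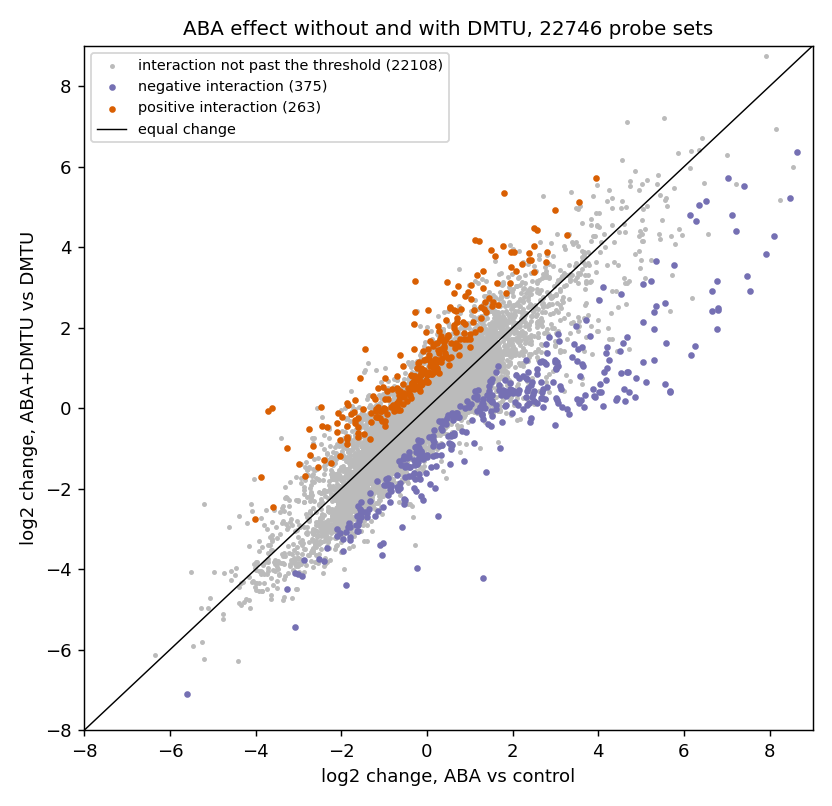
ABA effect on each probe set without DMTU (horizontal axis, log2) against the ABA effect with DMTU (vertical axis, log2), with the diagonal of equal effects. Probe sets past the interaction test are coloured (375 negative and 263 positive), and the others are grey.

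DMTU against control compared arrays given the scavenger without ABA with control arrays, a background for the comparison above. Any batch that the DMTU arrays shared would be part of these changes. The values of several plastid-encoded transcripts fell strongly, and LTI30, PYE and BHLH101 were among the genes that rose. The labelled material came from a 3' labelling kit, and how fully it reached organelle transcripts was not measured. The photosystem I core transcript psaA fell from 9.77 ± 0.51 to 5.63 ± 0.22 (SD, n = 3), a change of -4.15 ± 0.35 (SE; adjusted p = 5.48e-05, limma), and psbH and cemA had changes of -2.79 ± 0.26 and -2.68 ± 0.36. The cytochrome complex transcript petL had -3.62 ± 0.84 (adjusted p = 0.0135, and 0.0512 without DMTU replicate 3). Of 69 plastid-encoded genes, 30 fell and 1, ycf3, rose by 1.38 ± 0.41, with a median of -0.66 (camera adjusted p = 1.42e-10, and adjusted p = 0.646 with an estimated correlation). The 3' minus 5' difference of actin, a sign of RNA quality, was 3.58 ± 0.12 in DMTU and 3.2 ± 0.46 in control arrays (SD, n = 3). Of the 5 nuclear photosynthesis genes, 3 fell, and 3 adjusted over the list alone (camera adjusted p = 0.0252, and adjusted p = 0.598 with an estimated correlation). That call was lost without DMTU replicate 3 (adjusted p = 0.0511) and without dim probe sets (adjusted p = 0.0636). CP1 (-3.66 ± 0.14), the phylloquinone synthesis gene PHYLLO (-2.70 ± 0.16), the SUMO ligase SIZ1 (-2.69 ± 0.16) and the photosystem I subunit PSAN (-2.61 ± 0.30) were the other large falls among genes with a symbol.

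The iron-deficiency regulators PYE and BHLH101 rose with DMTU by 2.07 ± 0.26 and 1.44 ± 0.19. LTI30 rose by 2.71 ± 0.50, the actin-binding NET3A by 2.02 ± 0.33, the chloroplast protein PIFI by 1.86 ± 0.32, QPT of NAD synthesis by 1.82 ± 0.18, CDI by 1.67 ± 0.20 and AGL28 by 1.46 ± 0.27, and the adjusted p of these 8 rises was 0.0042 or less (limma). AT4G10270 rose by 4.66 ± 0.55, the largest rise of a gene known by locus alone. GSTU18, a glutathione S-transferase, fell by 1.56 ± 0.22 and GH3.5 by 1.61 ± 0.21. COR15A had 0.06 ± 0.27 (adjusted p = 0.911). UBC21, often used as a reference gene, rose by 0.88 ± 0.13. Of 102 ribosomal protein genes 15 rose and 0 fell (camera adjusted p = 6.36e-06, and adjusted p = 0.739 with an estimated correlation), a call that fry did not make (adjusted p = 0.149). Of 4 cell cycle genes 3 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.598 with an estimated correlation). Of 9 histone genes 3 rose (camera adjusted p = 0.00431, and adjusted p = 0.598 with an estimated correlation). Limma called 4013 probe sets, 2135 higher and 1878 lower, and 1119 changed at least 2-fold. The count was 2559 without DMTU replicate 2 and 8008 with array quality weights.

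In cells given ABA, some of the same genes differed with DMTU, and a set of ABA-induced ones was lower. SIZ1 (-2.62 ± 0.16), PHYLLO (-2.30 ± 0.16) and psaA (-3.67 ± 0.35) were again lower, and CDI (2.15 ± 0.20) and PIFI (2.08 ± 0.32) again higher, in ABA+DMTU than in ABA arrays. LEA18 (-3.17 ± 0.24), HIS1-3 (-3.12 ± 0.34), scpl28 (-2.36 ± 0.20), the glycosyltransferase UGT71C1 (-3.37 ± 0.35) and the receptor kinase GSO1 (-2.59 ± 0.40) were also lower, and these 8 falls had adjusted p of 0.00171 or less (limma). The peroxidase AT1G68850 went from 9.51 ± 1.17 with ABA to 4.14 ± 0.25 with ABA+DMTU (SD, n = 3), a change of -5.36 ± 0.43. The photosystem II core transcript psbA was higher by 2.79 ± 0.57, the heat stress immunophilin ROF2 by 2.27 ± 0.36, the growth regulator ARL by 2.02 ± 0.33, mitochondrial cox1 by 1.95 ± 0.39 and UPB1 by 1.71 ± 0.23. LTI30 was higher by 1.84 ± 0.50 (adjusted p = 0.0315), which was not called without ABA replicate 1 (0.0527), ABA+DMTU 2 (0.110) or ABA+DMTU 3 (0.114).

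Of the LEA family, 13 of 37 members were lower and 4 higher in ABA+DMTU than in ABA arrays (camera adjusted p = 0.00886, and adjusted p = 0.484 with an estimated correlation). Of 69 plastid-encoded genes, 17 were lower and 2 higher, with a median of -0.35 (camera adjusted p = 0.000831, and adjusted p = 0.751 with an estimated correlation). The plastid call was lost without ABA+DMTU replicate 3 (adjusted p = 0.392), without both arrays numbered 1 (adjusted p = 0.0734) and with fry (adjusted p = 0.3). The 3' minus 5' difference of actin was 3.31 ± 0.07 in ABA+DMTU and 2.65 ± 0.09 in ABA arrays (SD, n = 3). Of 16 mitochondrion-encoded genes, 2 were higher, with a median of 0.58 (camera adjusted p = 0.0136, and adjusted p = 0.704 with an estimated correlation). This call was lost without ABA replicate 2 (adjusted p = 0.0615), ABA+DMTU 1 (0.126) or ABA+DMTU 2 (0.0823), and with fry (adjusted p = 0.0713). Limma called 3234 probe sets, 1674 higher and 1560 lower, and 1044 changed at least 2-fold. The count was 2160 without ABA+DMTU replicate 3 and 7542 with array quality weights.

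DMTU effects without and with ABA were measured on separate arrays and shared 720 rises and 676 falls, where independent lists would share 157 and 129, with 15 and 13 opposite calls. The changes correlated across probe sets (r = 0.51, rho = 0.53). The DMTU arrays cannot be told apart from any batch they shared, so these shared changes hold for DMTU or for such a batch.

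**Figure D4:**
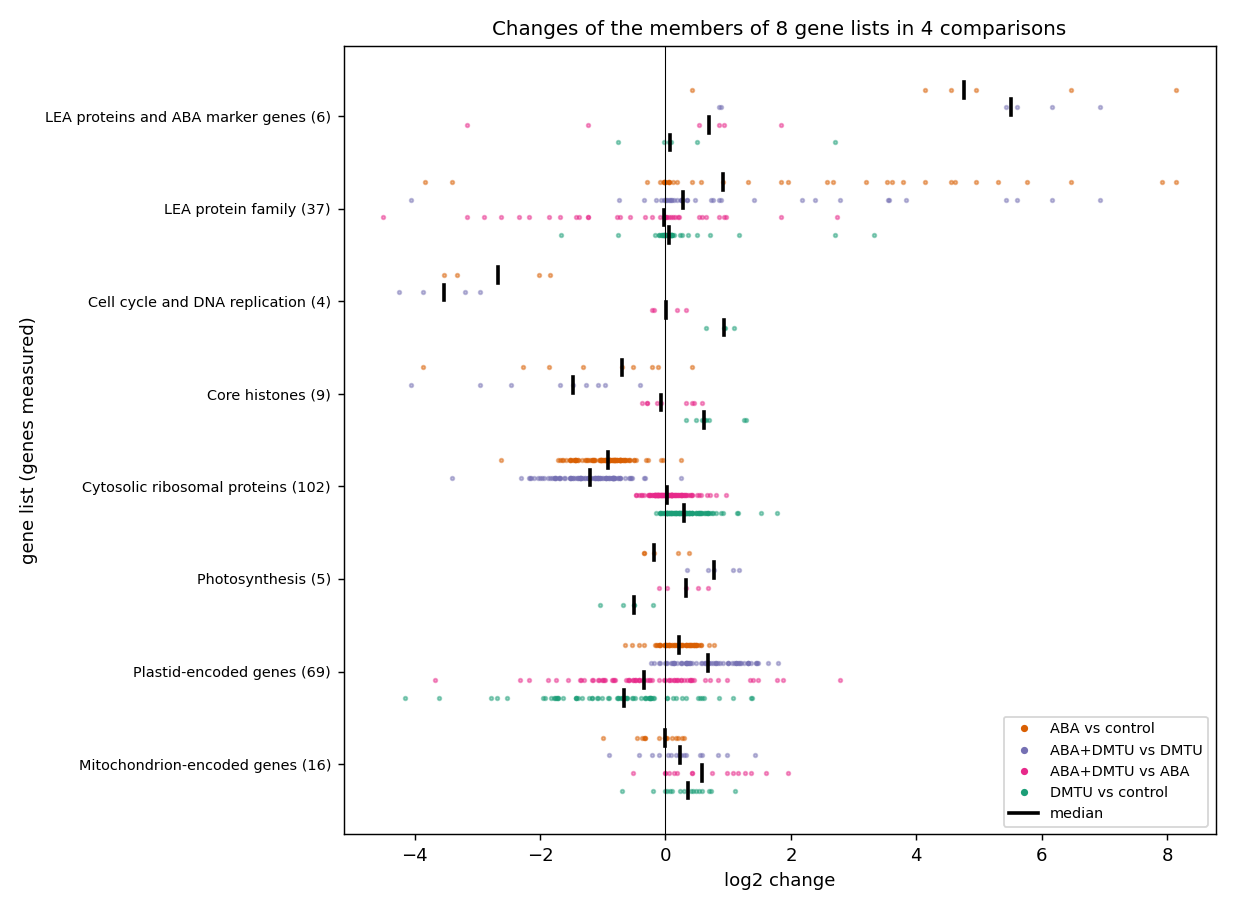
Log2 changes (horizontal axes) of the members of 8 gene lists in the 4 comparisons, with a point per gene and the list's median. Cytosolic ribosomal protein genes have medians of -0.91 and -1.21 in the ABA comparisons without and with DMTU, and plastid-encoded genes have a median of -0.66 in DMTU against control.

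The study's remaining goal, a comparison of transcript with protein abundance, was not analysed here.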

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

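The tests of a label swap, of RNA degradation, of a shared culture or day, of a common plastid RNA yield, of a need for ABA, of the arrays numbered 1, of a weaker ABA treatment and of reassignments within replicate numbers were chosen after the results were seen, and the tests of RNA degradation and plastid yield replaced earlier versions once values were known.

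The ABA effect differed between cells with and without DMTU for 638 probe sets, by limma's interaction test (n = 3 per group). In 100 reassignments of the arrays, after the additive effects of ABA and DMTU were removed, 2 gave as many calls, the real one included, a share under 0.05, although the highest other gave 812. Those reassignments moved arrays across replicate numbers, which by the rule fixed beforehand pair the control and ABA arrays, a pairing that rests on number 1. With arrays moved only within a number and the number as a block, 583 probe sets were called and again 2 of 100 gave as many, the real one included, with 826 as the highest other. The count moved with single arrays: it was 416 without control replicate 2, 385 without control 3, 343 without ABA 3, 395 without DMTU 1, 291 without DMTU 2, 370 without ABA+DMTU 2 and 411 without ABA+DMTU 3.

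The ABA effect was more positive, or less negative, with DMTU for CP1 (3.64), PMEPCRF (2.25), UPB1 (1.84), the vacuolar sugar transporter SWEET17 (1.81), FDH (1.77), SD1-29 (1.48), GSTU27 (1.28) and TBL25 (1.25). The same held for AT1G62480 (3.62), AT5G22860 (3.05), AT3G43430 (2.91), AT2G43535 (2.68), AT2G01990 (2.23) and AT2G43530 (2.12), all on the log2 scale. CP1 lay near the lower quartile of the arrays (3.84 to 3.98) in all groups but control, which may limit how far ABA could lower it with DMTU. That limit was not measured. SWEET17 lost its call without control 2, control 3 or any ABA+DMTU array (adjusted p from 0.0502 to 0.0660). GSTU27 lost it without control 3 (0.0502) or DMTU 2 (0.0508).

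The ABA effect was less positive, or more negative, with DMTU for LEA18 (-3.25), HIS1-3 (-3.09), AtLEA4-1 (-2.45), SAG29 (-2.31), APL4 (-2.18), scpl28 (-2.07), ATOEP16-2 (-2.02), PUB19 (-1.70) and AUR3 (-1.12). The same held for AT2G22510 (-5.27), AT1G68850 (-4.95), AT3G50400 (-4.82), AT5G12420 (-4.58), AT3G15670 (-4.43) and AT4G24130 (-4.37). AT2G22510 and AT5G12420 in all groups but ABA, like AT3G15670, and LEA18 and HIS1-3 without ABA lay at or below the lower quartiles of the arrays (3.84 to 3.98). AT1G68850 without ABA lay near or below them. The sizes of these values may therefore be bounded by the low end of the scale, which was not measured. The same may hold for other genes listed here that start low without ABA. AtLEA4-1 lost its call without any single array other than ABA 1 and ABA 2 (adjusted p from 0.0523 to 0.102). AT3G50400 lost it without control 3 or any DMTU array (0.0512 to 0.0612), and AT5G12420 without those or ABA+DMTU 1 or 2 (0.0507 to 0.0594). AUR3 lost it without ABA 2, ABA 3, DMTU 1, DMTU 2, ABA+DMTU 2 or ABA+DMTU 3 (0.0560 to 0.0710).

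ABA-induced transcripts that rose less with DMTU are the pattern that bears on the study's question. The calls of its 239 probe sets do not rest on the arrays numbered 1, since 97.1% stayed past the test without both of them. The 239 were chosen with both arrays in the fit, so this value holds for these probe sets only. A weaker ABA treatment of the DMTU cultures stays open and cannot be told apart: over probe sets chosen on the average effect the slope was 0.917, but 0.802 for the induced ones alone and 1.068 for the lowered ones, and on the axis from control (0) to ABA (1) the ABA+DMTU arrays lay at 0.815 to 0.826 and the DMTU arrays at -0.084 to -0.065. Selection on the ABA against control arrays stays open in part: of probe sets chosen on the other arrays, 3.76% had a negative interaction, between the 1% and 5% set beforehand. A gene-specific effect of DMTU may contribute. A batch that shifted the DMTU and ABA+DMTU arrays alike cancels in the interaction, away from the low end of the scale. A batch that acted unevenly on these arrays cannot be told apart from such an effect.

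Plastid-encoded transcripts differed between arrays with and without DMTU. A change in the yield of plastid RNA that moved all transcripts by the same log2 amount is argued against as the whole cause. In DMTU against control, 52.2% of the 69 transcripts lay over 2 standard errors from their median change. A change in yield, or in how the 3' labelling reached these transcripts, that acted unevenly cannot be told apart by this value. An effect that needs ABA is argued against by a correlation of 0.93 between the DMTU changes without and with ABA. A batch of arrays or labelling shared by the DMTU arrays could account for them and cannot be told apart from DMTU, since 0 groups hold arrays both with and without it. An effect of DMTU on plastid transcripts stays open in the same way.

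Replicate 1 of the control and ABA groups deviated from replicates 2 and 3, a pattern for which no biological explanation was tested. A swap of both labels is argued against, since on the axis from control (0) to ABA (1) control 1 lay at 0.205 and ABA 1 at 1.13. RNA degradation cannot be told apart: of 6 control probe set pairs, the 3' minus 5' difference was highest in replicate 1 for 6 in control and 4 in ABA, so 4 in both. A culture, day or batch shared by both arrays may be the source, with deviations that correlated at 0.52 across probe sets. Without both arrays the count for ABA against control was 8591, beside 8014 with them.

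Splits of the 6 arrays compared are too few for a share under 0.05, since 10 exist per comparison and 1 of the 10, the real one, gave as many limma calls in each. The real and the highest other count were 8014 and 0 for ABA against control, 8956 and 0 for ABA+DMTU against DMTU, 3234 and 5 for ABA+DMTU against ABA, and 4013 and 2 for DMTU against control. For ABA against control, if the arrays are taken as paired by number, the 3 other splits that part every pair also gave 0.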

How the results depend on the processing

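Leaving out replicate 1 of both the control and ABA groups, and the block in a 6-array fit (8364 for ABA against control), were chosen after the data were seen. Quantile normalization, median centring, a trended robust fit, a filter on dim probe sets and the 6-array fits each left every count of changed probe sets they could give within 1.5 times its value. With array quality weights the counts rose to 12891 (ABA against control), 7542 (ABA+DMTU against ABA), 8008 (DMTU against control) and 3097 (interaction), and shared DMTU changes to 3758; the cause was not tested. Asking for a 2-fold change left 3764, 4221, 1044 and 1119, and an adjusted p of 0.01 left 1511 (ABA+DMTU against ABA), 1776 (DMTU against control) and 167 (interaction), by construction. Probe sets of 1 gene without cross-hybridising types gave 4353, 4941, 1681, 2218 and 324, and 732 shared, with fewer probe sets tested. Without both arrays numbered 1 the interaction count was 1243. The slope of the ABA effect with DMTU on that without it, 0.871 over probe sets changed by ABA alone, was 0.887 without both arrays, 0.917 for probe sets chosen on the average effect and 1.009 for those chosen with DMTU, where the choice itself moves it.

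Leaving out 1 array at a time gave 6650 to 8754, 7754 to 8292, 2160 to 3021, 2559 to 3541 and 291 to 795 probe sets in the order above, slopes of 0.835 to 0.904, and 950 to 1560 shared DMTU changes. Among named genes, calls were lost without some array for 4 of 44 in ABA against control, 3 of 42 in ABA+DMTU against DMTU, 8 of 36 in ABA+DMTU against ABA, 11 of 41 in DMTU against control and 6 of 30 for the interaction, and for 7 of 26 list calls. The uncalled COR15A change in DMTU against control, 0.06, became -0.08 with weights, -0.07 without control replicate 1 (-0.07 to 0.13 over single arrays) and -0.07 without both arrays numbered 1; the cause was not tested.

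With the replicate number as a block, the counts were 8068, 8916, 3320, 4231 and 583, the slope was 0.871 and 1500 DMTU changes were shared. By the rule fixed beforehand the numbers pair the control and ABA arrays only, a hint that rests on number 1. In ABA against control the block ended no call of a named gene or list and kept 7747 of the 8014 probe sets. Elsewhere it ended those of XTH19 (adjusted p = 0.0567) and AT1G04770 (0.0501) in DMTU against control, AT2G29500 (0.0507) in ABA+DMTU against ABA and the trichome birefringence-like list (0.0627), and changed no other named call. Dim probe sets lie near the background of the arrays, which may limit changes to and from a low level.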

Other observations

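The tests of suberin and hypoxia genes were set before their values were read, on lists written after the largest changes had been seen, and the members already seen were kept apart.

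Gene groups outside the comparisons above moved in part. Of 47 UDP-glycosyltransferase genes, 12 rose and 5 fell with ABA, with UGT84A4 at 2.98 ± 0.59 (SE, n = 3 per group) and the cytokinin-conjugating UGT76C2 at -1.39 ± 0.23, and 13 rose and 4 fell with ABA in the presence of DMTU. Of 55 class III peroxidase genes, which use hydrogen peroxide in the wall, 10 rose and 14 fell with ABA, from AT4G26010 at 5.67 ± 0.55 to Prx37 at -5.27 ± 0.63, and with DMTU alone 1 rose and 8 fell. Autophagy genes rose with ABA for 3 of 8 members and with ABA and DMTU for 5, among them ATG8E (1.2 and 0.96). ALDH7B4, a stress-induced aldehyde dehydrogenase, rose by 1.61 and 1.49, within a list of 8 in which 2 rose and 2 fell with ABA and 3 rose with DMTU present. In the comparisons with ABA alone and with DMTU present, 5 rose and 1 fell, and 4 rose and 2 fell, of 20 beta-glucosidase genes. In the same order the counts were 5 and 2, then 4 and 2, of 26 cytochrome P450 genes, 4 and 5, then 4 and 5, of 29 carboxypeptidase-like genes, and 1 and 0, then 3 and 0, of 14 SWEET transporters. They were 2 and 1, then 4 and 0, of 15 tetraspanins, 3 and 2, then 4 and 3, of 13 ubiquitin-conjugating enzymes, 5 and 1, then 5 and 2, of 40 AGAMOUS-like factors, and 5 and 5, then 6 and 2, of 22 trichome birefringence-like genes. None of these lists passed camera in either ABA comparison.

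Of the fixed lists on oxidative stress, none passed camera in any comparison. With ABA, the NADPH oxidase list had a median of -0.04 and a mean of 0.81, and the oxidative stress markers a median of 0.49 and a mean of -0.12, so these differ in sign. The NADPH oxidase median became 0.11 with arrays centred on their medians. With ABA, the NADPH oxidase AT1G19230 rose by 2.94 ± 0.57 and AT4G11230 had -0.47 ± 0.11, and 1 rose and 1 fell adjusted over the list alone. For the interaction, AT1G19230 had -2.01 (adjusted p = 0.253) and AT4G11230 -0.50 (adjusted p = 0.152), so 0 of 3 members passed over all probe sets and 2 were negative adjusted over the list alone (camera adjusted p = 0.0888, fry adjusted p = 0.0239). In ABA+DMTU against ABA 0 passed, and 2 fell adjusted over the list alone. Glutathione reductase GR1 rose by 0.86 ± 0.16 with ABA and by 1.06 ± 0.16 with ABA and DMTU. Of 5 antioxidant enzyme genes, 1 rose and 1 fell with ABA, and the same counts held adjusted over the list alone. Of 8 glutathione S-transferase genes, 1 rose and 2 fell with ABA, and 2 rose and 2 fell adjusted over the list alone. GSTU18 rose by 1.66 ± 0.22 and GSTU22 fell by 1.46 ± 0.24. Of 3 oxidative stress markers, 1 rose and 1 fell with ABA, and so adjusted over the list alone, with AT2G21640 at -1.64 ± 0.40. The rise was NDB2 (0.79 ± 0.22). It was not called without ABA replicate 1 (0.66, limma adjusted p = 0.0606) or without both arrays numbered 1 (0.39, adjusted p = 0.0911). With DMTU alone, 1 rose and 0 fell, and NDB2, an alternative NADH dehydrogenase, rose by 1.11 ± 0.22. Of 6 heat shock genes, 2 rose in ABA+DMTU against ABA, and 2 adjusted over the list alone. They were ROF2 (2.27 ± 0.36) and AT2G29500 (0.64 ± 0.19, adjusted p = 0.0478), which was not called without ABA 1 (0.0828), ABA 2 (0.128), ABA 3 (0.0988), ABA+DMTU 1 (0.0675), ABA+DMTU 2 (0.164) or ABA+DMTU 3 (0.0735). Of 7 auxin response genes, 1 rose with ABA and 3 with ABA and DMTU, with the same counts adjusted over the list alone.

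Among fixed lists with 1 or 2 measured members, the cytokinin response regulator ARR15 fell by 1.88 ± 0.40 with ABA and UGT78D2 of flavonoid synthesis rose by 0.97 ± 0.16. The sulfur deficiency gene AT1G04770 had 1.22 ± 0.31 in ABA+DMTU against ABA (adjusted p = 0.0219). It was not called without ABA replicate 2 (0.0648), ABA 3 (0.0689), ABA+DMTU 2 (0.0870) or ABA+DMTU 3 (0.0829). BZIP60 of the unfolded protein response, the guard cell regulator FAMA, the SnRK2 and ABF list and the seed storage and oil body list had no call over all probe sets in any comparison. Of 3 reference genes, only UBC21 was called, in both DMTU comparisons, and its call in ABA+DMTU against ABA was lost without ABA 2 (0.0650), ABA+DMTU 2 (0.0690) or ABA+DMTU 3 (0.0703).

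A hypothesis that suberin and wax genes as a group respond less to ABA with DMTU came from 8 such genes among the large negative interactions, with a median of -4.19, such as the lipase-like AT2G23540 at -4.21 ± 0.52. On the 6 measured members not seen before, the median was -0.31, above the bound of -0.50 set beforehand for a negative answer. Camera pointed toward a smaller response (p = 0.00664, and p = 0.0532 with an estimated correlation). The spread of 0.69 set beside the median is the standard error of the mean over the 6 genes. It treats genes as replicates and is not the error of the median. Of these 6, 3 had no ABA call, and the requirement that the value exceed its spread was added after it was seen. AT2G48130 (-3.66 ± 0.27) and AT1G74460 (-2.85 ± 0.61) passed the interaction test, and AT5G14130 had -0.54 ± 0.36, so a smaller response of part of the group may hold. For the group as a whole the bound gave a negative answer and camera at the preset correlation pointed the other way, so it is undecided.

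A hypothesis that core hypoxia response genes rise with DMTU came from 4 genes such as AT4G10270. On the 21 measured members not seen before, the median change in DMTU against control was 0.58, over the bound of 0.50, with 8 higher and 0 lower (camera p = 0.000182, and p = 0.0577 with an estimated correlation). The pyruvate decarboxylase gene PDC2 rose by 1.13 ± 0.23, AT3G27220 by 1.66 ± 0.18 and AT3G10040 by 1.17 ± 0.20. In ABA+DMTU against ABA the median of the same 21 was 0.15, and the 4 genes seen before were not called there (adjusted p from 0.308 to 0.775), while PDC2 (0.99, adjusted p = 0.017) and AT1G74940 (1.2, adjusted p = 0.00217) rose and AT4G17670 (-1.03, adjusted p = 0.0251) fell. AT3G27220 and AT3G10040 had 0.19 and -0.01 there. The difference between these comparisons, which the interaction measures, was not tested for the list as a whole. Of the 21, AT3G27220 (-1.47, limma adjusted p = 0.0142), AT3G10040 (-1.18, 0.0486) and AT4G17670 (-1.60, 0.0484) passed the interaction test. Of the 4 seen before, AT4G10270 (-3.74, 0.0288) and AT4G33560 (-2.19, 0.0283) did. The other members did not pass it. The median of 0.58 is consistent with a mild low-oxygen response in the cultures given DMTU alone, and less aeration of those flasks could give the same values and was not tested.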
